A study of Nothobranchius furzeri with 15 samples.

How the data were processed

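Brains of 9-week-old male turquoise killifish (Nothobranchius furzeri, strain GRZ) were profiled by RNA-seq, with 15 libraries in 3 groups: solvent (DMSO), rotenone at 15 pM and rotenone at 150 pM. Libraries were grouped by the treatment given for each sample, which yields 5 DMSO, 4 rotenone 15 pM and 6 rotenone 150 pM libraries. The series description instead gives 5 libraries in each group. The library called 150 pM replicate 1 carries title number 1, whereas the 15 pM libraries carry title numbers 2 to 5 and the other 150 pM libraries 8 to 12, so its dose is uncertain. Replicates were numbered here in the order in which the samples are listed, which pairs no libraries.

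Total RNA was turned into libraries with the TruSeq RNA v2 kit, which does not mark strand, per the labels' protocols. CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4 are named, per the submitters' processing notes. The genome build, the gene annotation, the settings of read counting and the handling of reads shared between gene copies are not given in the sources used here. The authors deposited whole-number counts of reads per gene, without normalization per the file headers and values, for 26739 gene identifiers in 15 columns, of which 22948 had a count in at least 1 library. The authors also deposited an RPKM table of the same genes and libraries. Without strand, reads of overlapping antisense genes cannot be told apart, and genes with near-identical copies may have lost or gained reads.

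The RPKM table was checked against the counts. In 6891 genes with over 500 counts and an RPKM over 2 in every library, dividing by each library's own total left a median largest deviation of 0.220 log2 units from a single length per gene. When the 15 library totals were instead taken in turn down the rows of the table, the median of the same measure was 3.76e-05 and its maximum 0.000346 log2 units. By this check only 6.67% of the RPKM values had been divided by their own library's total, the median absolute error was 0.0846 log2 units, and single values were off by up to 1.20-fold. The counts were therefore used for all main results and the RPKM values only in alternatives. Gene lengths implied by the 2 tables were obtained for 22948 genes (median 2370 bases). Of these lengths, 49.9% were multiples of 3.

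The gene identifiers match 0 entries of the gene table used for names, and the deposited tables do not pair them with names. Gene names are therefore not given, and at most 2 identifiers that rose and 2 that fell are printed. The 37 gene lists fixed for mitochondrial complexes, stress responses, neuronal and glial markers and other tissues, the test of those lists and their alternatives were not run for the same reason. The rule for named genes was to take, in each comparison, the 10 largest rises and falls among symbol-bearing genes past the threshold with a mean log2 CPM of at least 0. That rule had genes without a symbol counted only, so with no symbols it named none. The 4 identifiers printed are the 2 largest rises and the 2 largest falls of 15 pM against DMSO under the same limit on mean log2 CPM. Printing them departs from the rule, and they were chosen after their values were seen.

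Total counts per library ranged from 19401441 to 23210889. Levels are given as CPM, the count of a gene scaled to a common library total. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom over genes was 7.38. In R 4.3.3 with edgeR 4.0.16, genes were kept with filterByExpr (19325 genes), scaled by TMM and fitted with the robust quasi-likelihood F test of edgeR in 1 model with the 3 groups and all 15 libraries. The contrasts were 15 pM against DMSO, 150 pM against DMSO, 150 pM against 15 pM and the mean of both doses against DMSO, and a further F test with 2 degrees of freedom asked whether a gene differed among the 3 groups. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. Standard errors were taken from the log2 fold change and its F value. At this depth and number of libraries the median 95% half-width of a fold change was 1.20-fold for 15 pM against DMSO and 1.18-fold for 150 pM against DMSO. The fit was tested on simulated counts with 200 changed genes. For 15 pM against DMSO (19243 genes tested), 51% of the genes changed 1.5-fold and 60% of those changed 2-fold were recovered, with 4 false calls. For 150 pM against DMSO (19233 genes tested) these shares were 57% and 64%, with 7 false calls. Each result comes from a single draw with genes drawn independently. The simulated libraries thus lack the variation that genes share within a real library, and these false calls do not measure those among the real libraries.

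Distances between groups were compared with a pseudo-F statistic on Euclidean distances of log2 CPM (prior count 2) and an exact permutation test over every split of the libraries concerned. Depth and other properties of the libraries were compared with two-sided exact permutation tests of the difference in means, with Benjamini-Hochberg adjustment over the 12 tests. The correlation of the fold changes of the 2 doses, which share the DMSO libraries, was set beside 50 simulations of unchanged groups and beside all 20 ways of giving 2 of the DMSO libraries to one dose and 3 to the other. Each library's position was measured as the correlation, across genes, of its log2 CPM profile with the mean of each group, after subtraction of the mean of the 3 group means, with the library itself left out. The nearest group was the one with the smallest root mean square distance. The relation of expression to gene length in a library was measured as Spearman's rho across genes, of log2 CPM with each gene's mean over libraries subtracted against implied length. Genes are not independent replicates. A length trend was removed, as an alternative, by an offset per library from a loess curve (span 0.5) of log2 CPM on log2 length. On simulated counts that differed only by such a trend, edgeR called 245 of 19236 genes before the offset and 0 after it.

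The alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, a mean count of at least 50, only the libraries of the groups compared, no robust estimation, 150 pM replicate 1 counted as 15 pM, 1 surrogate variable (sva 3.50.0), the length offset, limma 3.58.1 on log2(RPKM + 0.1) with and without a filter and on log2(RPKM + 1), limma voom with library weights, and leaving out each library in turn. These alternatives, the groups, the edgeR contrasts and threshold, the pseudo-F test and the correlation of the doses were chosen before the data were examined. The classes of gene length and expression level, the positions of libraries, the sharing of calls between the comparisons, the genes set apart by single libraries or by the 15 pM group and the check of RPKM divisors were added later. RPKM recomputed with each library's own total, and fits without the libraries that stood apart, were added after the data had been seen. Fewer alternatives were run for the 4 printed identifiers. These were DESeq2, its size factors in edgeR and limma on log2(RPKM + 0.1) with the filter. The others were 150 pM replicate 1 counted as 15 pM and leaving out each library in turn. Ranges of adjusted p given for these identifiers mix the values of these tools.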

Results

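The brains of 9-week-old male turquoise killifish of the GRZ strain, a short-lived laboratory strain of an annual fish, were compared after treatment with rotenone, an inhibitor of mitochondrial complex I, at 15 pM or 150 pM, or with the solvent DMSO alone. Gene-level read counts of 15 libraries were available: 5 from DMSO, 4 from 15 pM and 6 from 150 pM, as each sample was labelled. The series description gives 5 libraries per group, and the dose of 150 pM replicate 1 is the one in doubt. Nothing in the labels says that each library came from a separate fish, so p-values measure the spread between libraries, which may be technical in part. Total counts ranged from 19689907 to 23210889 in the 5 DMSO libraries, from 19719081 to 22527848 in the 4 libraries at 15 pM and from 19401441 to 23200181 in the 6 at 150 pM. Their means did not differ by more than the spread between libraries (two-sided exact permutation p = 0.563, 0.662 and 0.819 for 15 pM against DMSO, 150 pM against DMSO and 150 pM against 15 pM, adjusted 0.751, 0.795 and 0.819 over 12 tests).

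The first comparison asked which genes differed between the lower dose and the solvent. At 15 pM, 2728 of 19325 genes passed the threshold in edgeR, of which 1182 rose and 1546 fell. The rises were small, with a median log2 fold change of 0.29, and 23 of them reached 2-fold. The falls were larger, with a median of -0.53, and 278 reached 2-fold. The smallest adjusted p of edgeR was 0.000886, and 6003 genes had an unadjusted p under 0.05. The balance of directions was not stable: 43.3% of the calls were rises here, 52.1% without the low-count filter, 59.8% with each library's gene length trend removed, 55.6% (837 rises, 668 falls) without 15 pM replicate 1 and 36.5% without DMSO replicate 2. Limma on the deposited RPKM, most of whose values were divided by another library's total, gave 4.78% (66 rises, 1316 falls). With RPKM recomputed from each library's own total it gave 37.4%.

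**Figure D1:**
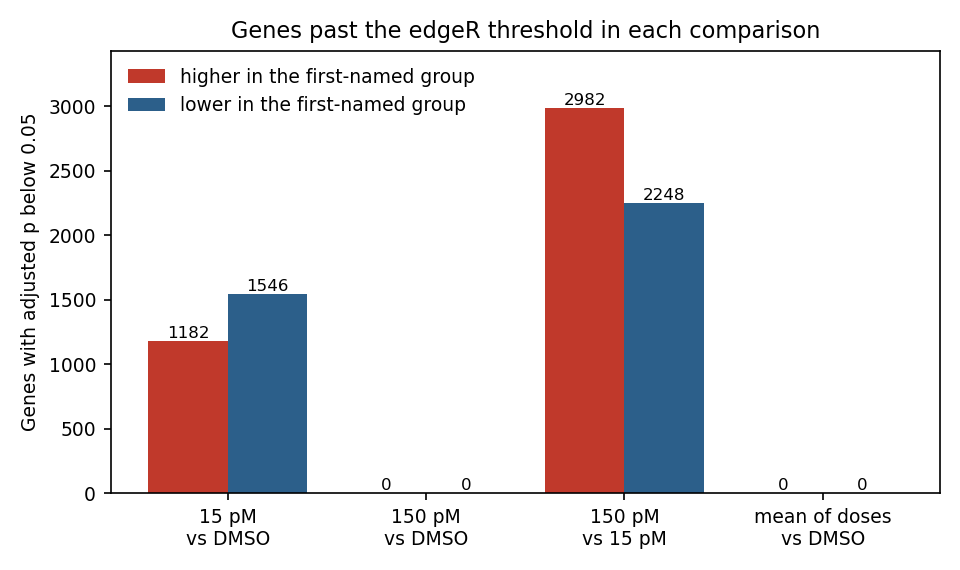
Genes past the edgeR threshold (vertical axis, number of genes) in each of 4 comparisons (horizontal axis), with red bars for genes higher and blue bars for genes lower in the group named first. Both comparisons that hold the 15 pM group on its own had calls (1182 and 1546, 2982 and 2248), and the other 2 had 0.

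Among called genes with a mean log2 CPM of at least 0, the 2 largest rises belonged to genes with low levels in DMSO. Nfu_g_1_023228 (implied length 915 bases) was at 0.596 ± 0.483 CPM (SD, n = 5) in DMSO and at 79.9 ± 43.6 (n = 4) at 15 pM. Its log2 fold change was 7.09 (SE 2.14, edgeR adjusted p = 0.0424), and the ratio of summed counts was 136 (exact 95% interval 106 to 178, counting error only). Nfu_g_1_007507 (444 bases) was at 3.41 ± 1.98 CPM in DMSO (n = 5) and 450 ± 308 at 15 pM (n = 4), a log2 fold change of 7.04 (SE 1.71, edgeR adjusted p = 0.0195). All 4 libraries at 15 pM lay above all 5 DMSO libraries for both genes. The adjusted p of edgeR for Nfu_g_1_023228 lay between 0.0537 and 0.0918 when any 1 DMSO library or 15 pM replicate 1, 2 or 4 was left out (range over the fits run for it, of any tool, 4.73e-05 to 0.0918), and that for Nfu_g_1_007507 was 0.0523 without DMSO replicate 1 (range 4.47e-05 to 0.0523). Neither identifier is paired with a gene name in the deposited tables, and counts of either could be shared with a close copy elsewhere in the genome.

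Among the same genes, the 2 largest falls belonged to genes whose level varied widely among DMSO libraries and which had 1 to 3 counts in each library at 15 pM, so that their fold changes rest on few counts there. Nfu_g_1_006401 (1713 bases) was at 5.18 ± 8.85 CPM in DMSO (n = 5), from 0.0444 to 20.8, and at 0.120 ± 0.0288 at 15 pM (n = 4), where each library held 2 or 3 counts. Its summed counts at 15 pM were 0.0234 of those in DMSO per total count (exact 95% interval 0.0112 to 0.0435, counting error only), and its fitted log2 fold change was -5.36 (edgeR adjusted p = 0.0354). Nfu_g_1_013814 (2857 bases) was at 3.65 ± 3.63 CPM in DMSO (n = 5) and 0.109 ± 0.0489 at 15 pM (n = 4), with 1 to 3 counts per library. The ratio of its summed counts was 0.0305 (exact 95% interval 0.0139 to 0.0586), and its fitted log2 fold change was -5.00 (edgeR adjusted p = 0.0357). For Nfu_g_1_006401 the DMSO libraries overlapped those at 15 pM, since DMSO replicate 5 held 1 count, and without DMSO replicate 2 the fitted log2 fold change was -3.34 (edgeR adjusted p = 0.0837). For Nfu_g_1_013814, DMSO replicate 2, at 0.141 CPM, lay within the range at 15 pM, which reached 0.153. The adjusted p of edgeR for Nfu_g_1_006401 was also 0.0509 without DMSO replicate 4 and 0.0516 to 0.0957 without any 1 library at 15 pM (range over the fits run for it, of any tool, 0.000387 to 0.189), and that for Nfu_g_1_013814 was 0.0511 to 0.0958 without 15 pM replicate 1, 2 or 4 or DMSO replicate 1, 4 or 5 (range 0.000498 to 0.431). With 150 pM replicate 1 counted as 15 pM, the log2 fold changes were -3.48 (edgeR adjusted p = 0.0815) and -1.58 (edgeR adjusted p = 0.431).

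**Figure D2:**
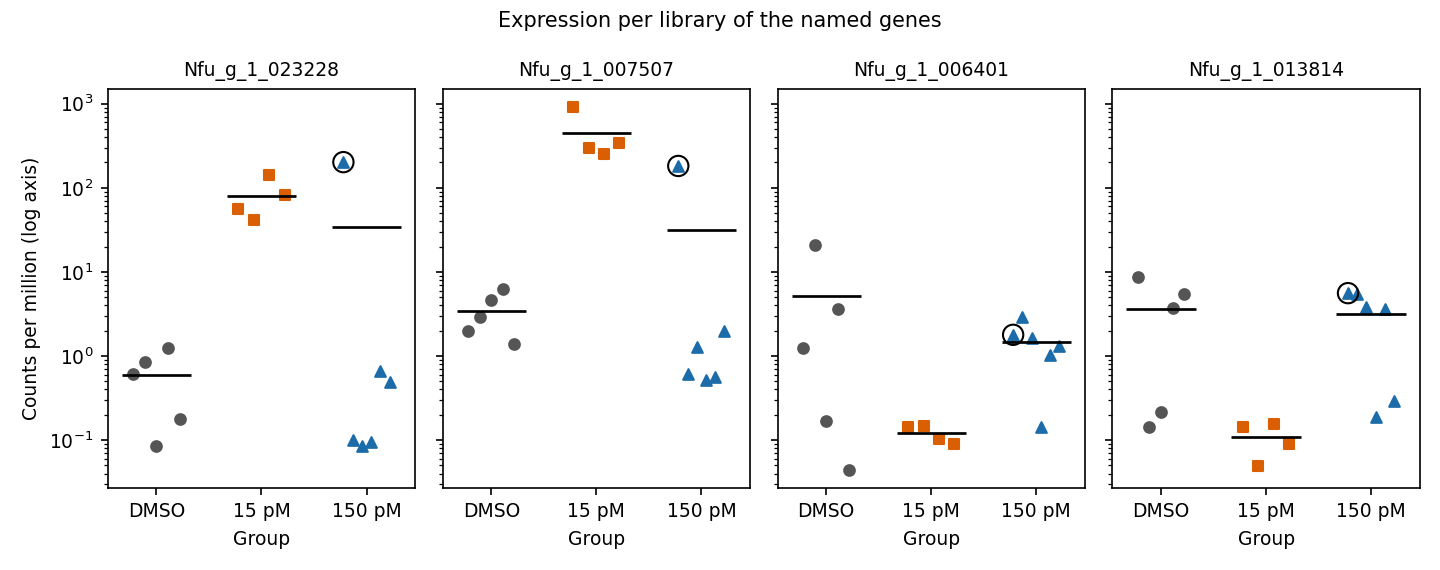
CPM (vertical log axis) of the 4 named genes in each library, by group, with a horizontal line at each group mean and a black ring around 150 pM replicate 1. For Nfu_g_1_023228 and Nfu_g_1_007507 the ringed library (202 and 182 CPM) sits with the 15 pM libraries, and the other 5 libraries at 150 pM lie at or below 1.98.

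The balance of rises and falls at 15 pM depended on gene length. The tested genes were divided into 4 classes of nearly equal size by implied length. In the 3 classes up to 4685 bases, 49.5%, 51.3% and 52.5% of the called genes rose. In the longest class (4686 to 88570 bases) 137 genes rose and 547 fell. Spearman's rho of expression with gene length, computed across genes within each library, was 0.0132 ± 0.0947 (SD, n = 5) in DMSO and -0.120 ± 0.0827 (n = 4) at 15 pM (exact permutation p = 0.0635, adjusted 0.238 over 12 tests). The unadjusted exact p was 0.0357 without 15 pM replicate 3, 0.0476 with 150 pM replicate 1 counted as 15 pM and 0.114 without DMSO replicate 1. After the length trend of each library was removed, edgeR called 2865 genes, of which 1713 rose and 1152 fell. Of the 2728 calls, 2234 were kept with their direction. By expression level, the share of calls that rose went from 27.9% in the least expressed of 4 classes to 49.6% in the next to highest and 45.0% in the highest.

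**Figure D3:**
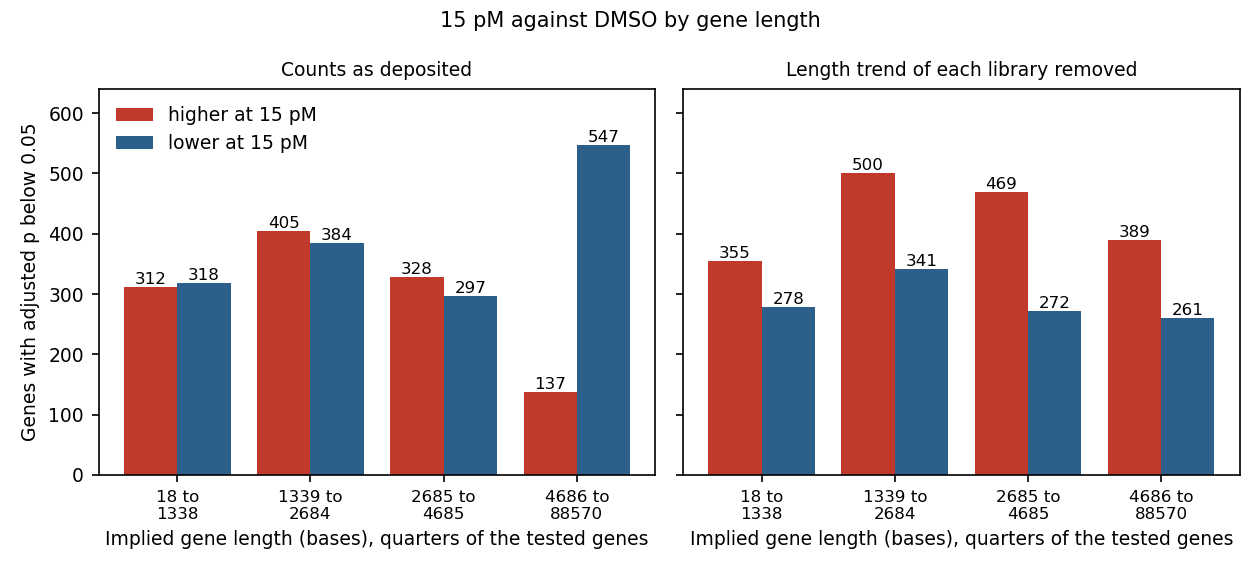
Genes called by edgeR for 15 pM against DMSO (vertical axis, number of genes) in 4 classes of implied gene length in bases (horizontal axis), from the counts as deposited (left) and after removal of each library's length trend (right). Among the longest genes 547 fell and 137 rose on the left, against 261 and 389 on the right.

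The number of calls at 15 pM changed with most of the libraries compared. It was 982 without 15 pM replicate 4, 1505 without 15 pM replicate 1, 1191, 1489 and 1684 without DMSO replicates 1, 2 and 4, and 4999 without 15 pM replicate 3, all in edgeR. The whole profiles of the 2 groups differed by a pseudo-F of 2.65 (27.4% of the variation, exact permutation p = 0.0317 over 126 splits, adjusted 0.0491 over 4 comparisons). That p lay between 0.0536 and 0.0857 without any 1 DMSO library or without 15 pM replicate 1, 2 or 4, and without 15 pM replicate 3 the pseudo-F was 4.41 (exact permutation p = 0.0179).

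The second comparison asked the same of the higher dose. At 150 pM 0 genes passed the threshold in edgeR, 1783 had an unadjusted p under 0.05, and the smallest adjusted p was 0.326. DESeq2 called 40 genes (11 higher, 29 lower), limma voom with library weights 434 (159 higher, 275 lower) and limma on RPKM 0. The 2 genes that rose most at 15 pM averaged 33.8 ± 82.2 (Nfu_g_1_023228) and 31.1 ± 73.7 (Nfu_g_1_007507) CPM at 150 pM (SD, n = 6), and 150 pM replicate 1 alone, at 202 and 182, set these means. In the other 5 libraries at 150 pM, Nfu_g_1_023228 lay between 0.0858 and 0.667 CPM and Nfu_g_1_007507 between 0.523 and 1.98. Nfu_g_1_006401 was at 1.47 ± 0.919 and Nfu_g_1_013814 at 3.16 ± 2.39 CPM (n = 6), with log2 fold changes against DMSO of -1.81 (edgeR adjusted p = 0.598) and -0.20 (edgeR adjusted p = 0.968). The genes that rose at 15 pM had a median log2 fold change of 0.03 at 150 pM, and those that fell had one of 0.05. Without 150 pM replicate 1 the medians of the difference in mean log2 CPM were -0.0013 and 0.10.

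Whole profiles of 150 pM and DMSO differed by a pseudo-F of 1.89 (17.4% of the variation, exact permutation p = 0.0368 over 462 splits, adjusted 0.0491). That p lay between 0.0635 and 0.162 without DMSO replicate 2, 3 or 5 or 150 pM replicate 3, 4, 5 or 6. EdgeR called 77 genes (5 higher, 72 lower) without 15 pM replicate 3, which enters only through the shared fit, and 1 without DMSO replicate 5. With 150 pM replicate 1 and DMSO replicate 1 left out edgeR called 561 genes, 443 higher and 118 lower, and with 15 pM replicate 3 left out as well it called 1861, 1040 higher and 821 lower, so that the prevailing direction at 150 pM differed between settings. These libraries were chosen because they lay nearest to another group, DMSO replicate 1 to 150 pM itself, so that a larger count is in part built into their removal.

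The third comparison set the doses against each other. Between 150 pM and 15 pM, 5230 of 19325 genes passed the threshold in edgeR, with 2982 higher and 2248 lower at 150 pM. Of the calls 57.0% were higher here, 49.2% without the low-count filter, 45.9% with the length trend removed, 49.9% without 15 pM replicate 1 and 66.0% with only the libraries compared. Limma on the deposited RPKM, with its wrong divisors, gave 87.7% (2260 higher, 318 lower), and 59.8% with RPKM recomputed from each library's own total. Of the genes higher at 150 pM, 813 differed by at least 2-fold, against 94 of those lower. Nfu_g_1_007507 was lower at 150 pM, with a log2 fold change of -3.85 (SE 1.34, edgeR adjusted p = 0.0473), and Nfu_g_1_013814 was higher, with one of 4.8 (SE 1.42, edgeR adjusted p = 0.0235). Nfu_g_1_023228 and Nfu_g_1_006401 did not pass, with log2 fold changes of -1.24 (edgeR adjusted p = 0.562, range over the fits run for it, of any tool, 2.84e-05 to 0.739) and 3.55 (edgeR adjusted p = 0.101, range 0.0130 to 0.383). Nfu_g_1_006401 passed in DESeq2 (3.62, adjusted p = 0.0130) and, in edgeR, without DMSO replicate 2 (adjusted p = 0.0318). With 150 pM replicate 1 left out, the log2 fold changes were -8.13 for Nfu_g_1_023228 and -8.80 for Nfu_g_1_007507, with edgeR adjusted p of 3.72e-05 and 1.26e-05. The adjusted p of edgeR for Nfu_g_1_007507 lay between 0.0550 and 0.121 when any other library except 15 pM replicate 3 was left out (range over the fits run for it 1.26e-05 to 0.121). That for Nfu_g_1_013814 lay between 0.0588 and 0.0640 without 15 pM replicate 1, 2 or 4, and its log2 fold change was 1.13 (edgeR adjusted p = 0.529) with 150 pM replicate 1 counted as 15 pM (range over the fits run for it, of any tool, 0.000265 to 0.529).

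Long genes were set apart in this comparison too, but it shares the 15 pM libraries with the first and is not a separate occurrence. In the longest class 1216 genes were higher and 317 lower at 150 pM, and in the other 3 classes between 45.9% and 49.0% of the calls were higher. Spearman's rho with gene length was 0.0749 ± 0.0932 (SD, n = 6) at 150 pM, above that at 15 pM (exact permutation p = 0.0143, adjusted 0.0857 over 12 tests). With the length trend removed, edgeR called 4735 genes, 2171 higher and 2564 lower, and 4115 of the 5230 calls were kept with their direction. The 50 most abundant genes took 8.89% ± 0.326 (SD, n = 6) of the counts at 150 pM and 10.06% ± 0.879 (n = 4) at 15 pM (exact permutation p = 0.00952, adjusted 0.0857). The profiles differed by a pseudo-F of 4.1 (33.9% of the variation, exact permutation p = 0.00952 over 210 splits, adjusted 0.0381). Without 15 pM replicate 4 the number of calls was 3483.

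Genes called at 15 pM against DMSO were compared with those called between the doses. Of the 1182 genes that rose at 15 pM, 904 were lower again at 150 pM than at 15 pM, and of the 1546 that fell, 1432 were higher again. Both comparisons use the 15 pM libraries with opposite signs, which adds to this overlap: across genes their log2 fold changes had a correlation of -0.80, and unchanged groups simulated in the same way gave -0.58. When 2 of the 4 libraries at 15 pM were set against DMSO and the other 2 against 150 pM, the genes called at 15 pM that were shared in the opposite direction numbered 121 of 166, 137 of 196, 303 of 473, 456 of 1056, 519 of 1446 and 632 of 3002 in the 6 ways of doing so, against 14.2 to 123 for independent lists. Across genes, which are not independent replicates, the log2 fold changes of the 2 doses against DMSO had a correlation of 0.07 and a covariance of 0.01. Simulated unchanged groups, with the DMSO libraries redrawn too and shared by both doses, gave 0.487 ± 0.0154 (SD over 50 simulations) and 0.0315. The simulations drew genes independently, so this SD leaves out variation that genes share within a library. With the real DMSO libraries divided between the doses the median correlation was -0.0866 (range -0.313 to 0.165 over 20 divisions).

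The mean of both doses was compared with DMSO, which tests the average of the doses and not a change at each of them. A gene changed at a single dose can pass, and opposite changes cancel. In edgeR 0 genes passed, 2769 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0726. DESeq2 called 382 genes and limma voom with library weights called 914, 26.8% of them higher, and limma on RPKM called 6. Nfu_g_1_007507 had a log2 fold change of 5.12 (edgeR adjusted p = 0.188) and Nfu_g_1_006401 one of -3.59 (edgeR adjusted p = 0.168). For whole profiles, the DMSO libraries were set against the libraries of both doses pooled. The difference between the doses thus counted as spread within a group. The pseudo-F was 1.24 (8.70% of the variation, exact permutation p = 0.237 over 3003 splits), so no difference was detected. EdgeR called 549 genes without 15 pM replicate 3, 3 without 150 pM replicate 1 and 2 without 15 pM replicate 2. Over the 3 groups together 4027 genes differed in edgeR, and this number was 1387 without 15 pM replicate 4, 1960 without 15 pM replicate 1 and 6303 without 15 pM replicate 3.

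The libraries themselves did not all lie with their group. The first principal component held 35% of the variance and the second 18.4%. On the first, 3 libraries at 15 pM lay between 36.7 and 67.5 and 15 pM replicate 3 at 14.4. The DMSO libraries lay between -33.0 and 6.94, and 5 of the libraries at 150 pM between -42.0 and -23.3. Of the 15 libraries, 12 were nearest to the mean of their own group, with the library itself left out. The profile of 150 pM replicate 1 correlated with the 15 pM mean at 0.490 and with the 150 pM mean at -0.392. The profile of DMSO replicate 1 correlated with the 150 pM mean at 0.636 and with the DMSO mean at -0.0831. The profile of 15 pM replicate 3 correlated with the DMSO mean at 0.365 and with the 15 pM mean at -0.102, although Nfu_g_1_023228 and Nfu_g_1_007507, at 140 and 255 CPM, lay above every DMSO library in it. Of the 76 genes whose ranges part the other 15 pM libraries from DMSO by at least 2-fold, 62 put it on the DMSO side and 14 on the 15 pM side.

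**Figure D4:**
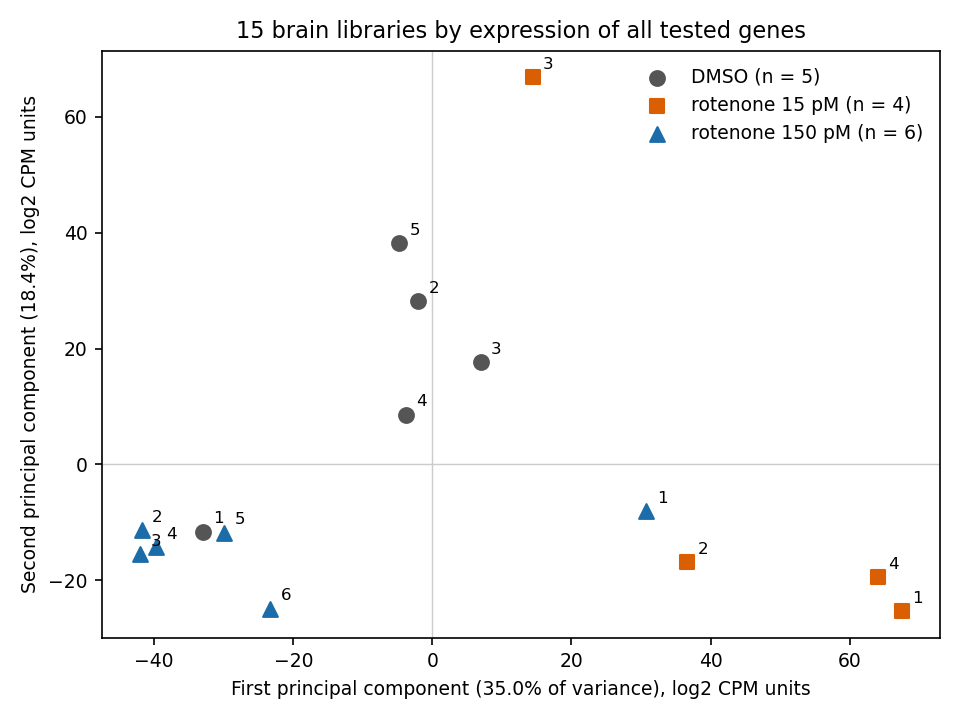
First principal component (horizontal axis, 35% of the variance) and second (vertical axis, 18.4%) of log2 CPM over 19325 genes, with 1 point per library numbered by replicate. Replicate 1 of 150 pM lies at 30.8 on the first component beside the 15 pM libraries, and DMSO replicate 1 lies at -33.0 among those at 150 pM. Replicate 3 of 15 pM lies at 14.4 on the first and at 66.8 on the second.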

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

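The tests of wrong labels, of an exchange of libraries and of what the length trend accounts for were chosen only after the results were seen, although the length correction they use was not.

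In 8 of 33 groups of values tested, 1 library lay far from the rest of its group by Dixon's gap test, where chance gives about 1 in 20 for a single group. The groups are not independent, and 12 of them, with 4 of the 8, are levels of the 4 genes chosen after their values were seen, so that this rate does not carry over to the whole. In 5 of these groups it was 150 pM replicate 1. It lay at 30.8 on the first principal component, where the other 5 libraries at 150 pM lay between -42.0 and -23.3. Its Spearman's rho of expression with gene length was -0.106, and theirs were 0.0622 to 0.150. Its 50 most abundant genes took 9.54% of the counts, against 8.71% to 8.85%. It held 202 CPM of Nfu_g_1_023228 and 182 of Nfu_g_1_007507. The 15 pM replicate 3 lay at 66.8 on the second principal component, 15 pM replicate 1 held 909 CPM of Nfu_g_1_007507, and DMSO replicate 2 held 20.8 CPM of Nfu_g_1_006401.

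Replicate 1 of 150 pM resembled the 15 pM group, and DMSO replicate 1 the 150 pM group. An exchange of these 2 libraries would put 150 pM replicate 1 with DMSO, but of the 11 genes whose ranges part 15 pM from DMSO by at least 2-fold, 90.9% put it on the 15 pM side, which argues against an exchange. The length trend does not account for either position: with it removed, 150 pM replicate 1 still correlated with the 15 pM mean at 0.486 and with the 150 pM mean at -0.386, and DMSO replicate 1 with the 150 pM mean at 0.629. A wrong dose label of 150 pM replicate 1 may be the cause, since 99.1% of the 231 genes that part 15 pM from the other 150 pM libraries, chosen without it, put it on the 15 pM side, although DMSO replicates 2 to 5 also lay on that side in 180 to 208 of these genes, and its title number and the 5 libraries per group of the series description also place it there. A wrong treatment label of DMSO replicate 1 could likewise explain its position, with 98.4% of 122 genes that part 150 pM from the other DMSO libraries on the 150 pM side when 150 pM replicate 1 is left out (17 of 17 genes with it kept), although no label casts doubt on it, and a response to the treatment as labelled, which was not tested, stays open for both libraries.

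The excess of falls among the longest genes at 15 pM goes with a length trend of whole libraries. A length bias as the whole cause of the calls is argued against by the 81.9% of them that remained, with their direction, once the trend of each library was removed. In the longest class 59.8% of the calls were rises after the removal, against 56.1% to 63.3% in the other classes. Because the correction itself sets this outcome, a technical length bias and a response of long genes to 15 pM rotenone cannot be told apart for that excess. The single DMSO libraries spanned values of Spearman's rho from -0.114 to 0.144, and the group means were 0.0132 for DMSO and -0.120 for 15 pM. Replicates 1, 2 and 4 of 15 pM, at -0.187, -0.159 and -0.134, lay below every DMSO library. Replicate 3 of 15 pM, at -0.000151, lay within the DMSO range.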

How the results depend on the processing

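The fits without libraries that stood apart and the recomputed RPKM were chosen only after the results were seen. Counts are in the order 15 pM against DMSO (2728), 150 pM against DMSO (0), 150 pM against 15 pM (5230), mean dose against DMSO (0) and 3 groups (4027). Size factors of DESeq2, a mean count of at least 50, no filter, no robust estimation, 1 surrogate variable and the length offset kept all 5 counts within 1.5 times. DESeq2 itself called 40 genes at 150 pM and 382 for the mean dose, and gave no adjusted p for Nfu_g_1_007507. Limma voom with library weights called 5768, 434, 8128, 914 and 8081; the cause was not tested. Only the libraries compared, thus fewer, gave 1469 for 15 pM against DMSO. These are all libraries for the last 2 counts, so that fit was not run there.

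Limma on the deposited RPKM gave 1382 for 15 pM against DMSO, 2578 for 150 pM against 15 pM and 1941 for the 3 groups at a pseudocount of 0.1, 1250, 2544 and 1913 at 1, and 1206, 2425 and 1811 without a filter. For the mean dose it gave 6, 1 and 8. At 15 pM 4.78% of its calls (pseudocount 0.1) were rises and between the doses 87.7% were higher at 150 pM, against 37.4% and 59.8% with RPKM recomputed from each library's own total, which called 2955, 5127 and 4113, and 5 for the mean dose. Only the divisors differ between these fits. At a pseudocount of 0.1 the deposited RPKM gave -2.41 for Nfu_g_1_006401 (limma adjusted p = 0.189) and -2.45 for Nfu_g_1_013814 (limma adjusted p = 0.147) at 15 pM. Over the settings run for these genes, of any tool, the adjusted p was 0.000387 to 0.189 and 0.000498 to 0.431.

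Counting 150 pM replicate 1 as 15 pM gave 3227, 0, 6011, 1 and 5068, with 2248 calls shared at 15 pM. With DMSO replicate 1 also left out, edgeR called 1749 at 15 pM and 582 (464 higher, 118 lower) at 150 pM. With 15 pM replicate 3 left out instead, it called 4917, 188 (30 higher, 158 lower), 7215, 328 and 6857. Leaving out all 3 libraries gave 4996, 1861, 7779, 608 and 7503. Leaving out 150 pM replicate 1 and DMSO replicate 1 gave 2229, 561, 6166, 0 and 5069. These libraries were chosen for lying nearest to another group, which in part builds larger counts in.

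Leaving out each library in turn gave 982 to 4999, 0 to 77, 3483 to 6674, 0 to 549 and 1387 to 6303 calls. The lowest ends above 0 came without 15 pM replicate 4 and each highest without 15 pM replicate 3. Without DMSO replicates 1, 2 and 4 and 15 pM replicate 1 there were 1191, 1489, 1684 and 1505 calls at 15 pM, and 1960 over the 3 groups without the last. The pseudo-F of 15 pM against DMSO ranged from 1.82 (without 15 pM replicate 1, exact p = 0.0714) to 4.41 (without 15 pM replicate 3, exact p = 0.0179). That of 150 pM against DMSO ranged from 1.41 (without DMSO replicate 2, exact p = 0.162) to 2.58 (without DMSO replicate 1), and was 1.87 (exact p = 0.0693) with a mean count of at least 50. The correlation of the doses, 0.07, changed sign: it ranged from -0.10 (without 150 pM replicate 1) to 0.19 (without DMSO replicate 1), and was -0.05 with a mean count of at least 50 and -0.08 with 150 pM replicate 1 counted as 15 pM. Counts within 1.5 times, pseudo-F values on the same side of the threshold and correlations that moved by less than the distance from the middle to an end of the range over the divided DMSO libraries made up 120 of the summary values with a library left out, beside 7 higher or newly past the threshold and 23 lower or no longer past it. Under other settings these were 69, 22 and 12. These settings include the fits on the deposited RPKM and those without libraries chosen for lying nearest to another group. By this rule the changes of sign of the correlation counted as unchanged, so the tally is no measure of robustness. No log2 fold change of the 4 named genes changed sign in the settings run for it. Depth limits Nfu_g_1_006401 and Nfu_g_1_013814, with 1 to 3 counts per library at 15 pM. The gene list alternatives were not run.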

Other observations

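The genes set apart by the 15 pM group, the tests of chance placement and of shared reads on them and the genes of single libraries were chosen only after the results were seen, unlike the regroupings.

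A small set of genes set the 15 pM group apart. In all, 8 genes parted the 4 libraries at 15 pM from the 5 DMSO and the other 5 libraries at 150 pM by at least 2-fold, 6 of them higher at 15 pM and 2 lower. Random sets of 4 of these libraries parted at most 1 gene from the other 10 in 100 draws. Nfu_g_1_023228 and Nfu_g_1_007507 are among the 6. The lowest level of these 6 at 15 pM was 10.8 to 255 CPM, and the highest in the other 10 libraries 0.982 to 16.7, so that not all of them were near 0 there. Of the 8 genes, 7 put 150 pM replicate 1 on the 15 pM side.

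Single libraries held gene sets of their own. In 15 pM replicate 3, 40 genes were at least 3-fold above every other library (at 5 or more CPM), with a median log2 excess of 2.91 over the median library. The next highest library for this set was DMSO replicate 5, at 0.58. In DMSO replicate 2, 19 genes were as far above every other library, with a median log2 excess of 3.53. Of the 40 genes, 2 were called for 15 pM against DMSO, where 14.1% of all tested genes were. The genes were picked for standing out in a single library, so a low number is built in.

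The 6 genes higher at 15 pM sit close together in the order of the deposited table, 4 of them within 9 rows and the other 2 in adjacent rows. Chance placement is argued against, since 0 of 10000 random sets of 6 tested genes had all 6 members within 10 rows of another, and the highest number was 2. If neighbouring genes share the same reads, the ratio of neighbours should be steady across the 5 libraries with high levels of them. The SD of the log2 ratio was 0.252 to 0.989 and exceeded 0.5 in 4 of 7 pairs, but its lower 95% bound did so in 2. The rule first written for this test asked only that the SD itself exceed 0.5 in most pairs, which would argue against shared reads. The stricter bound was put in its place, and the pairs share genes, so shared reads stay open. The meaning of the table's order is not given in the sources used here, adjacent rows had a median correlation across libraries of 0.0740 against -0.00978 for random pairs (15197 pairs), and no biological explanation was tested.

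Regroupings of the libraries with the group sizes kept, 100 for each result with the real one included, bear on chance. They were drawn from 126, 462 and 210 possible ones for the pairs of groups. For the mean dose and for the 3 groups they were drawn from 630630. For 15 pM against DMSO 1 of 100 gave as many genes (real 2728, highest other 889), for 150 pM against 15 pM 1 of 100 (5230 and 2091), and over the 3 groups 1 of 100 (4027 and 2799). The smallest share these draws can give is 1 of 100. Chance is thus argued against for these 3 counts at the 0.05 level of this test only. The test takes the libraries as independent, which the labels do not state. All 3 counts use the same 15 pM libraries and are not separate results. For 150 pM against DMSO (0 and 360) and for the mean dose (0 and 1) the real count is 0, so that 100 of 100 gave as many by construction and the regroupings say nothing about chance. The regrouping with 360 genes set DMSO replicates 2 to 5 with 150 pM replicates 1 and 6 against DMSO replicate 1 and the other 150 pM libraries. It was picked as the highest of those drawn and in part repeats the positions of DMSO replicate 1 and 150 pM replicate 1. It is therefore no separate evidence of a structure other than the labelled groups.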
